A study of Mus musculus with 6 samples.

How the data were processed

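RNA was extracted from liver or liver tumour of mice on a high-fat diet, per the labels of the samples. The labels' extraction text speaks of cell lines, although every sample is labelled as tissue. Libraries were made from total RNA with a stranded TruSeq kit, per the labels' protocols. Each library has a deposited table of counts, whole numbers of reads per Ensembl gene. Per the submitters' processing notes, the counts were made with TopHat, whose version is not given in the sources used here, and HTSeq 0.6.1 on genome build mm9. The gene annotation, the strand setting of the counting and any read filters are not given in the sources used here. All 6 libraries carry the same batch label, so batches could not be compared. Antisense and overlapping genes are uncertain where the counting ignored strand.

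The tables name 37991 genes, of which 32919 matched a symbol of the GRCm38 reference by Ensembl identifier, as did 16523 of the 17558 genes tested. Genes with a symbol held 85.2% to 90.7% of the counts. Genes held 39723997 to 62178752 counts per library. Entries that name no gene were left out of library sizes and tests. They made up 27.6% and 20.9% of the counted reads in control livers 1 and 2, 24.8% and 20.9% in KAP1-deleted livers 1 and 2, and 36.7% and 33.1% in tumours 1 and 2. Reads ambiguous between genes made up 1.73% to 2.87%. The entry for reads aligned to several places is 0 in all 6 libraries. A pair of identifiers without a symbol had near-equal counts, 4.02% to 6.67% of the counts each, which differed by 0.00934% to 0.209% and in either direction. Reads that match both places could give this, and whether each was placed at 1 of them or counted at both is not known. Counts of a gene can therefore hold reads of related genes. Sequence sharing was measured as the percent of a gene's 31-base words found in no other of the 55450 genes of the GRCm38 reference transcripts. Replicates differed by more than sampling noise (chi-square per degree of freedom of 90.8 to 352 within groups), so no library was counted as a duplicate. Counting intervals (95%, exact) and floors of 3 counts cover counting error only.

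Genes were tested with edgeR 4.0.16 in R 4.3.3. Low genes were removed with filterByExpr by group (minimum count 10, minimum total 15), libraries were scaled with TMM, and 1 mean per group was fitted to all 6 libraries with a robust quasi-likelihood fit. That leaves 3 residual degrees of freedom, with a common biological coefficient of variation of 0.230. TMM factors were 0.872 and 0.948 in control livers, 0.864 and 0.879 in KAP1-deleted livers, and 1.31 and 1.22 in tumours, replicates 1 and 2. P-values were two-sided and adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The SE of a log2 fold change was taken as its size over the square root of the test's F. Fitted log2 fold changes use a prior count of 0.125. Against a group with 0 counts, a fold is a lower bound from 3 counts over the group, and against 1 to 3 counts it is a ratio of counts with an exact interval.

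The text names genes by a rule set from the labels. It takes Trim28 and Alb, Xist and 4 Y-linked genes, and the 5 genes with most counts. Per comparison it adds up to 8 genes with the highest and 8 with the lowest log2 fold change among called genes. Those need a mean CPM of at least 1, no overlap between the groups and a symbol that is no predicted or pseudogene name. Called genes with such a symbol or none numbered 16, 283 and 386 in the comparisons of KAP1-deleted with control liver, tumour with KAP1-deleted liver and tumour with control liver. The rule also takes up to 4 members of a gene list with the smallest adjusted p. The text describes part of the genes that the rule takes, and some of them are not reported here. The 36 gene lists cover liver cell functions, zonation, cell type markers, tumour pathways and KAP1 targets, and each was written down with the rule. Lists with at least 5 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison. With a correlation estimated from the residuals no list was called in any of the 3 comparisons, and the unadjusted p was under 0.05 for 1, 7 and 7 lists.

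The mouse codes in the labels put a KAP1-deleted liver and a tumour of the same replicate number in 1 mouse. Their deviations from the group means correlated across genes with r = 0.185. This is 1 value, since with 2 libraries per group the deviations of both mice are equal and opposite. The mouse was not in the model reported, and a fit with it as a block is given where it changes a call. That fit leaves 1 residual degree of freedom, since each control library is the only one of its mouse. Its spread rests on the 2 mice with both tissues, so calls gained with the block are uncertain. Alternatives were DESeq2 size factors, upper-quartile scaling, 2 other filters, the 20 most abundant genes left out, the tests of DESeq2 1.42.0 and limma-voom, voom with the mouse as a random block, the mouse as a fixed block, only the groups compared, a 2-fold threshold, each library left out, fry, and camera with an estimated correlation. A block by mouse code series, a restriction to mostly unique genes and a split of the controls were added after seeing the data. Chromosome medians took genes with a mean CPM of at least 5, and each library's log2 value was set against the mean of the livers other than itself and centred on the median gene. Their bounds are 95% bootstrap bounds over genes taken as independent, and they do not measure the spread between tumours.

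The test was tried on simulated counts for the 17558 genes with 200 changed in each comparison. With dispersions from the trend, 95.7, 88.7 and 95.4% of the genes changed 8-fold were called in KAP1-deleted against control liver, tumour against KAP1-deleted liver and tumour against control liver, in that order. At 4-fold 85.3, 88.3 and 77.8% were called, and at 2-fold 30.4, 24.4 and 12.7%. False calls made up 5.77%, 5.22% and 4.55% of calls. With gene-wise dispersions they made up 12.7%, 11.5% and 10.6%, above the threshold of 5%. An 8-fold change was then called in 85.2, 95.6 and 91.5%, a 4-fold one in 75.7, 87.7 and 74.4% and a 2-fold one in 14.5, 23.9 and 33.9%. The trended simulation was added after a gene-wise one had shown false calls above 5%. For KAP1-deleted against control liver a simulated list of 20 genes raised 2-fold had a camera adjusted p of 4.2e-29, and 0 of 20 unchanged lists were called. The simulated genes varied independently of each other, so this trial cannot test the preset correlation. In that comparison the correlation estimated from the data was 0.604 for cholesterol genes and 0.129 for Zfp genes. It was 0.224 for male-biased and -0.001 for female-biased genes. A planted chromosome shift of -0.415 in simulated tumours was recovered as -0.365 and -0.357 over 9037 genes. That trial used independent genes, the same dispersion for every gene and no other change in the tumours. It cannot show how far an unaltered chromosome would move in the real tumours.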

Results

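Liver and tumour transcriptomes were measured by RNA sequencing in mice given a high-fat diet for 27 weeks and killed at 35 weeks of age. KAP1, encoded by Trim28 and named Kap1 in the study title, is a co-repressor that zinc finger proteins bring to their DNA targets. The control livers came from mice that carry the Alb-Cre transgene alone, which drives Cre recombinase from the albumin promoter in hepatocytes. The KAP1-deleted livers came from mice with the same transgene and a Trim28 gene that Cre can inactivate, and the tumours were taken from the livers of those mice. Each of the 3 groups held 2 libraries, and by the mouse codes in the labels each tumour and the KAP1-deleted liver of the same replicate number came from 1 mouse. Counts in genes totalled 39723997 and 62178752 in control replicates 1 and 2, 50977644 and 53744834 in KAP1-deleted replicates 1 and 2, and 55316370 and 43173982 in tumour replicates 1 and 2. The first principal component of log2 CPM held 60.6% of the variance and set both tumours apart from the 4 livers. Along the second, with 14.3%, control replicate 1 lay at 52.3, KAP1-deleted replicate 2 at -41, and the rest between -12.05 and 14.2. Levels below are CPM, gene counts scaled to a common library size with TMM factors, as mean ± SD over the 2 libraries of a group, and log2 fold changes are given ± SE with the adjusted p of edgeR's quasi-likelihood test. Unless values without a library are printed beside it, a gene described below as having risen or fallen kept its call when each of the 6 libraries was left out in turn. The labels name 4 mice but do not say how the animals were housed or bred, and with 2 libraries per group the p-values measure the spread between these samples.

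The targeted gene came first. Trim28 (ENSMUSG00000005566) stood at 32.5 and 35.9 CPM in control livers 1 and 2, at 5.06 and 6.02 CPM in KAP1-deleted livers 1 and 2, and at 5.22 and 4.59 CPM in tumours 1 and 2. It fell in the KAP1-deleted livers (log2 fold change -2.63 ± 0.19, adjusted p = 0.00393) and in the tumours against control liver (log2 fold change -2.80 ± 0.19, adjusted p = 4.3e-04). Between tumour and KAP1-deleted liver its log2 fold change was -0.18 ± 0.19, with an edgeR adjusted p of 0.573. Albumin transcripts (Alb) averaged 67947 ± 9303 CPM in control liver, 59164 ± 7579 CPM in KAP1-deleted liver and 26524 ± 11830.0 CPM in tumour. No comparison passed the threshold. The edgeR adjusted p of Alb was 1 between KAP1-deleted and control liver, 0.126 between tumour and KAP1-deleted liver and 0.0796 between tumour and control liver. Of the Y-linked genes, Ddx3y, Kdm5d, Uty and Eif2s3y were expressed in all 6 libraries, the lowest value being 26.3 CPM, and Xist reached 1.41 CPM at most.

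**Figure D1:**
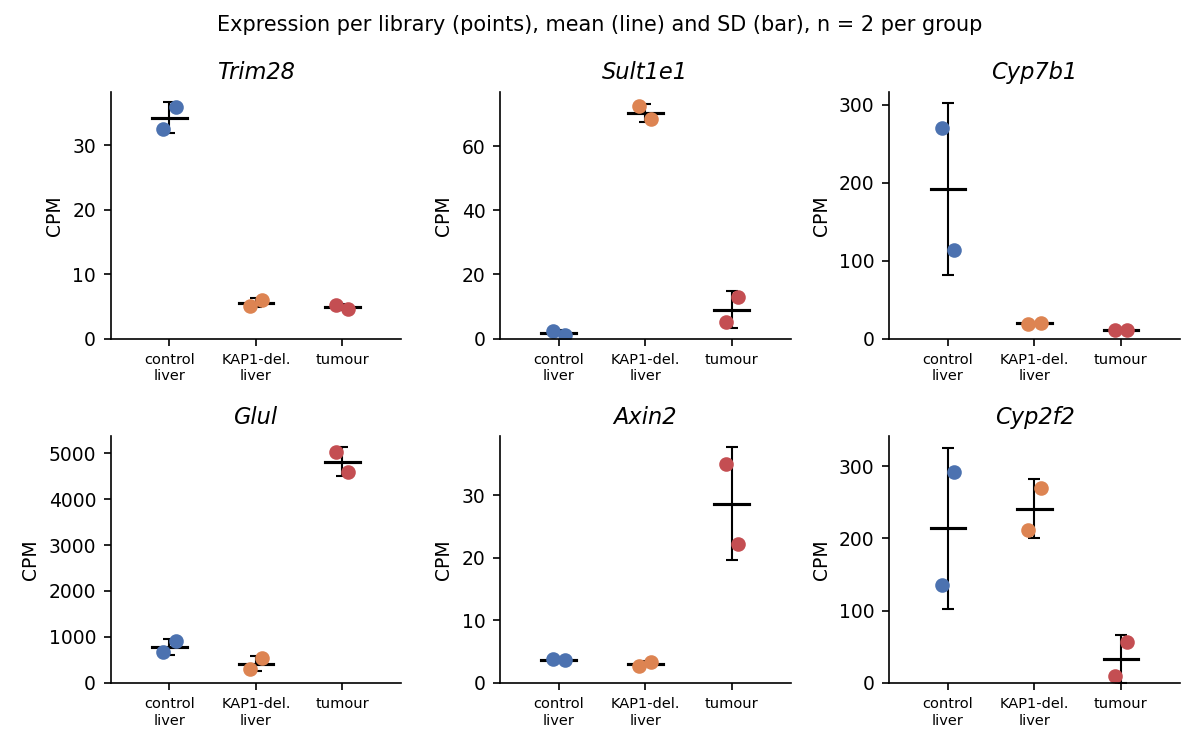
CPM of Trim28, Sult1e1, Cyp7b1, Glul, Axin2 and Cyp2f2 in control liver, KAP1-deleted liver and tumour, with points for single libraries, lines for means and bars for SD (n = 2 per group). Trim28 averaged 34.2 CPM in control liver and 5.54 and 4.90 CPM in the other groups, while Axin2 averaged 28.7 CPM in tumour and 3.05 CPM in KAP1-deleted liver.

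The comparison of KAP1-deleted with control liver asks what loss of hepatic KAP1 changed in non-tumour liver under the diet. Catsperg2, a subunit of the sperm cation channel, averaged 10.4 ± 1.76 CPM in KAP1-deleted liver and had 2 counts in the control libraries together, a count ratio of 482 with a 95% counting interval of 133 to 3989 (edgeR adjusted p = 0.00393). Fbxw16, an F-box and WD repeat gene, averaged 3.30 ± 1.31 CPM, at least 102-fold higher than in control liver, where both libraries held 0 counts (edgeR adjusted p = 0.00988). Mas1, which encodes the receptor for angiotensin-(1-7), rose 28.6-fold from 0.253 ± 0.195 to 7.93 ± 3.29 CPM (log2 fold change 4.84 ± 0.49, adjusted p = 0.0118).

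Sult1e1, the estrogen sulfotransferase, was 39.3-fold higher at 70.5 ± 2.88 against 1.83 ± 0.838 CPM (log2 fold change 5.30 ± 0.57, adjusted p = 0.0294). Its adjusted p was 0.293 and 0.306 without control replicates 1 and 2, and 0.233 and 0.227 without KAP1-deleted replicates 1 and 2 (range 2.0e-75 to 0.306 over the alternatives). Cyp7b1, the oxysterol 7-alpha-hydroxylase, fell from 192 ± 110.2 to 19.8 ± 0.736 CPM (log2 fold change -3.28 ± 0.39, adjusted p = 0.0244). The adjusted p of Cyp7b1 was 0.120 and 0.129 without KAP1-deleted replicates 1 and 2, and 0.0616 and 0.0622 without tumour replicates 1 and 2 (range 1.0e-33 to 0.129 over the alternatives). Rarres1, a retinoic acid responsive gene, averaged 72.8 ± 12.5 CPM in control and 1.80 ± 0.749 CPM in KAP1-deleted liver (log2 fold change -5.33 ± 0.49, adjusted p = 0.0149). The adjusted p of Rarres1 was 0.168 and 0.130 without control replicates 1 and 2 (range 4.0e-77 to 0.168 over the alternatives). Cdhr2, of the cadherin family, was 55.6-fold higher (log2 fold change 5.80 ± 0.48, adjusted p = 0.00722). For Cdhr2 it was 0.0646 without control replicate 2 (range 1.2e-41 to 0.0646 over the alternatives). Fbxw19, a paralog of Fbxw16, had 0 counts in both control libraries and averaged 6.70 ± 3.66 CPM, at least 206-fold higher (edgeR adjusted p = 0.0105). It had an adjusted p of 0.0702 and 0.0799 without control replicates 1 and 2 (range 7.6e-65 to 0.0799 over the alternatives). Trim24, a co-regulator of nuclear receptors from the protein family of KAP1, averaged 158 ± 18.0 against 46.8 ± 13.2 CPM (log2 fold change 1.75 ± 0.26, adjusted p = 0.0474). Its adjusted p became 0.0819 without control replicate 2, 0.0631 without KAP1-deleted replicate 1, and 0.0848 and 0.0833 without tumour replicates 1 and 2 (range 5.7e-10 to 0.138 over the alternatives). With only the 4 libraries of these groups in the fit the adjusted p was 0.0548 for Fbxw16 (range 1.1e-41 to 0.0548 over the alternatives) and 0.0599 for Mas1 (range 7.9e-41 to 0.0599 over the alternatives). Fbxw19, Cyp7b1 and Trim24 also lost their calls there, as did Cyp7b1 and Trim24 with a mean CPM of at least 5 and Trim24 with upper-quartile scaling. In the reference transcripts 59.3% of the 31-base words of Fbxw16 and 43.7% of those of Catsperg2 occur in no other gene, so reads of relatives could not be kept apart in full and their values are uncertain.

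Zinc finger protein genes named Zfp and a number, most of which encode DNA-binding proteins and many of which recruit KAP1, were called higher as a list by camera, though few members passed alone. Of 330 tested members of the 355, 12 rose and 0 fell (21 adjusted over the list alone). Their median log2 fold change was 0.14 (camera adjusted p = 8.0e-08, and adjusted p = 0.972 with an estimated correlation). DESeq2 called 22 of them higher and limma-voom 6. The number that rose was 4 and 3 without control replicates 1 and 2, and 5 without either tumour replicate. The list's adjusted p was 0.0932 without control replicate 2 (range 3.1e-12 to 0.972 over the alternatives). Zfp987 rose 13.3-fold to 8.24 ± 2.84 CPM (log2 fold change 3.74 ± 0.34, adjusted p = 0.00988). Zfp993 rose 5.46-fold to 22.3 ± 5.02 CPM (log2 fold change 2.45 ± 0.23, adjusted p = 0.0105). Zfp992 averaged 118 ± 38.5 against 15.5 ± 0.842 CPM (log2 fold change 2.93 ± 0.29, adjusted p = 0.0105). The adjusted p of Zfp992 was 0.0614 and 0.0659 without control replicates 1 and 2 (range 9.7e-27 to 0.0659 over the alternatives). In the gene order of GRCm38, 9 of the 12 lay on chromosome 4 in 1 stretch from Gm13244 to Zfp984, a feature chosen after its values were seen. That stretch held 44 tested genes, of which 15 rose and 0 fell. A log2 fold change above 0 was seen in 43 of them, and the median was 2.07. The count that rose was 4 and 6 without control replicates 1 and 2, and 7 without either tumour replicate. Between 6.85% and 56.8% of the 31-base words of the 12 raised Zfp genes occur in no other gene, so their single values are uncertain.

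**Figure D2:**
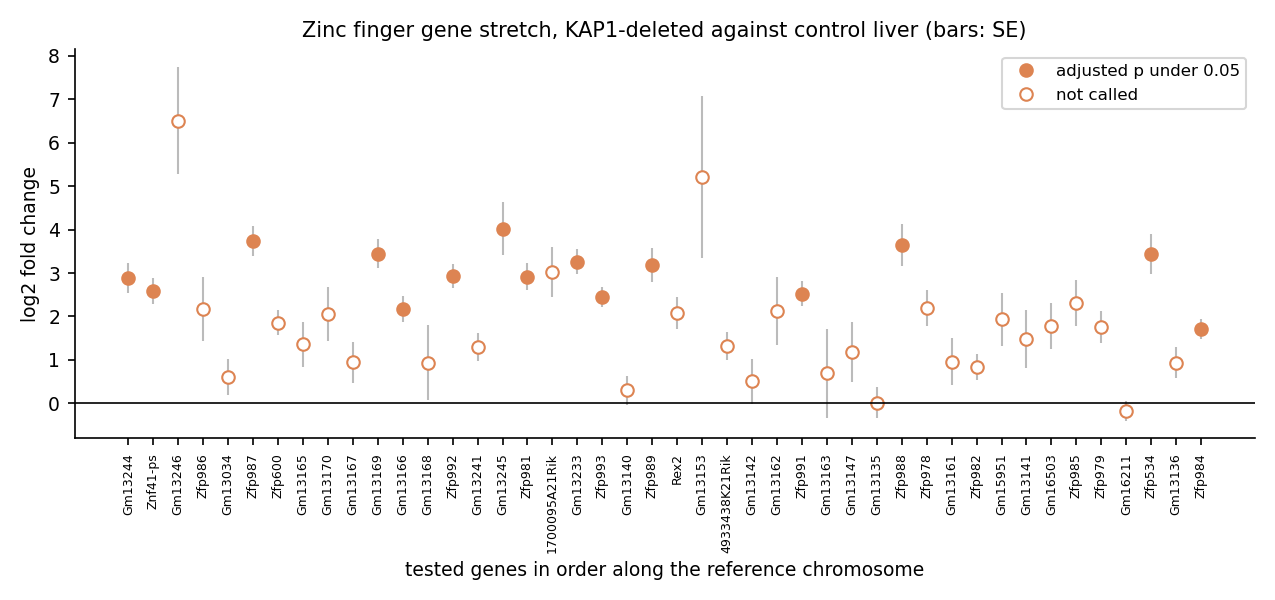
Log2 fold change of KAP1-deleted against control liver for the 44 tested genes of the chromosome 4 stretch, in the gene order of GRCm38, with bars for SE. Filled points mark the 15 genes that passed the threshold and open points the rest, and 43 of the 44 points lie above 0.

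Genes of cholesterol synthesis and uptake were lower together. All 22 tested members had a log2 fold change below 0, with a median of -1.02 (camera adjusted p = 3.3e-09, and adjusted p = 0.972 with an estimated correlation). Without control replicate 1 the list's adjusted p was 0.0599 (range 4.8e-23 to 0.972 over the alternatives). No member passed edgeR's threshold alone (0 adjusted over the list alone). An unadjusted p under 0.05 was found for 4, and DESeq2 and limma-voom called 0 and 0. Nsdhl, a sterol dehydrogenase of the pathway, had a log2 fold change of -1.58 ± 0.56 and Srebf2, which encodes its main transcription factor, -0.66 ± 0.26 (edgeR adjusted p 0.782 and 0.805). Genes with female-biased expression in mouse liver shifted up, with a median of 0.37 over 27 genes (camera adjusted p = 3.1e-04, and adjusted p = 0.631 with an estimated correlation). The adjusted p of this list was 0.407 without control replicate 1 (range 2.9e-07 to 0.858 over the alternatives). By edgeR 0 of them were called (2 rose and 1 fell adjusted over the list alone). In edgeR 9 had an unadjusted p under 0.05, while DESeq2 called 3 higher and 1 lower, and limma-voom 0. Male-biased genes shifted down, with a median of -0.64 over 24 genes (camera adjusted p = 0.0263, and adjusted p = 0.972 with an estimated correlation). Called members stood on both sides, with 1 that rose and 1 that fell (2 rose and 2 fell adjusted over the list alone), and DESeq2 called 2 higher and 3 lower. For the male-biased list the adjusted p was 0.433 without control replicate 1, and 0.110 and 0.0831 without KAP1-deleted replicates 1 and 2 (range 1.8e-09 to 0.996 over the alternatives), and 0.0917 with a block by mouse code series, an alternative chosen after seeing the data.

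In all, 42 genes rose and 17 fell among 17558 tested, each by at least 2-fold, and 955 had an unadjusted p under 0.05. Leaving out control replicates 1 and 2 gave 20 and 14, and 26 and 20 higher and lower. Leaving out KAP1-deleted replicates 1 and 2 gave 64 and 11, and 52 and 13. Leaving out tumour replicates 1 and 2, which enter the estimate of spread, gave 22 and 8, and 23 and 8. DESeq2 called 152 and 78 and limma-voom 26 and 12. Of the 35 lists tested, the 4 above were called. The number was 11, 9, 7, 6, 7 and 5 without control replicates 1 and 2, KAP1-deleted replicates 1 and 2 and tumour replicates 1 and 2, and 1, 3, 3, 3, 4 and 4 of the 4 stayed called. With the mouse code series as a block 3 of the 4 did. The 31 lists with no edgeR call held 621 tested members, of which 44 had an unadjusted p under 0.05, DESeq2 called 12 and limma-voom 0.

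Tumours were compared with the KAP1-deleted liver of the same mice, which sets tumour apart from non-tumour tissue of the same genotype. Targets of Wnt and beta-catenin signalling rose. Of 15 tested, 13 rose and 0 fell (13 adjusted over the list alone). The median log2 fold change was 2.62 (camera adjusted p = 1.5e-33, and adjusted p = 0.173 with an estimated correlation). Nkd1, an inhibitor of the pathway that its signal induces, rose 21.4-fold from 2.11 ± 0.191 to 45.2 ± 8.87 CPM (log2 fold change 4.42 ± 0.23, adjusted p = 2.5e-04). Lgr5, a receptor for R-spondins, rose 10.4-fold to 54.8 ± 1.82 CPM (log2 fold change 3.38 ± 0.20, adjusted p = 3.0e-04). Axin2, a feedback inhibitor, rose 9.40-fold to 28.7 ± 9.04 CPM (log2 fold change 3.23 ± 0.27, adjusted p = 0.00119). Markers of pericentral hepatocytes, the cells around the central vein, rose in 9 of 15 cases and fell in 0 (12 adjusted over the list alone). Their median was 1.87 (camera adjusted p = 2.8e-15, and adjusted p = 0.184 with an estimated correlation). Among them were Glul, the glutamine synthetase of these cells, at 4819 ± 309 against 419 ± 164 CPM (log2 fold change 3.52 ± 0.37, adjusted p = 0.00238). The glutamate transporter Slc1a2 rose as well (log2 fold change 4.18 ± 0.35, adjusted p = 0.00119).

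Periportal markers, genes of hepatocytes near the portal vein, fell in 11 of 18 cases and rose in 0 (18 adjusted over the list alone). The median was -2.86 (camera adjusted p = 8.1e-17, and adjusted p = 0.184 with an estimated correlation). The number that fell was 7 without KAP1-deleted replicate 1. Pck1, the cytosolic phosphoenolpyruvate carboxykinase of gluconeogenesis, fell from 1286 ± 122 to 127 ± 72.7 CPM (log2 fold change -3.34 ± 0.46, adjusted p = 0.00559). So did Ass1 of the urea cycle (log2 fold change -2.10 ± 0.28, adjusted p = 0.00492) and Sdsl, a serine dehydratase homologue (log2 fold change -3.19 ± 0.45, adjusted p = 0.00592). Of the words of Ass1 56.9% are unique, and its value is uncertain. In the list of gluconeogenesis and glycogen, 1 of 14 rose and 7 fell (1 rose and 9 fell adjusted over the list alone). The list had a camera adjusted p = 6.9e-05, and adjusted p = 0.184 with an estimated correlation. It includes Fbp1, fructose-bisphosphatase, which fell (log2 fold change -1.79 ± 0.27, adjusted p = 0.00801). The number that fell there was 3 without KAP1-deleted replicate 2, and 2 and 3 without tumour replicates 1 and 2. The number that rose was 2 without either control replicate, 0 without either KAP1-deleted replicate, and 2 with the mouse as a block. Fatty acid and triglyceride synthesis had 5 of 22 genes lower and 0 higher (7 adjusted over the list alone; camera adjusted p = 4.6e-05, and adjusted p = 0.184 with an estimated correlation). The lower ones numbered 8 without control replicate 1, 3 without KAP1-deleted replicate 1, 2 without tumour replicate 1, and 12 with the mouse as a block. Acly, the ATP citrate lyase that supplies acetyl-CoA, fell from 92.2 ± 5.08 to 32.6 ± 5.84 CPM (edgeR adjusted p = 0.00529). Of 20 lipid droplet genes, 2 rose and 4 fell (2 rose and 6 fell adjusted over the list alone), with 17 of 20 below 0 and a median of -0.82. The lipid droplet falls numbered 7 without either control replicate, 1 and 2 without KAP1-deleted replicates 1 and 2, 2 and 0 without tumour replicates 1 and 2, and 9 with the mouse as a block. The rises numbered 1 without either KAP1-deleted replicate, and 1 without tumour replicate 1. Of 24 genes of fatty acid oxidation 2 rose and 1 fell (2 rose and 1 fell adjusted over the list alone), with a median of -0.11, while the direction of the camera test was up. The fatty acid oxidation rises numbered 1 without KAP1-deleted replicate 1, 1 without tumour replicate 1, and 4 with the mouse as a block. The falls of that list numbered 3 and 2 without control replicates 1 and 2, 0 without either KAP1-deleted replicate, 0 without either tumour replicate, and 3 with the mouse as a block. Neither list was called by camera. The members with the smallest adjusted p included Lpl, lipoprotein lipase, and Pdk4, a kinase that inhibits pyruvate dehydrogenase, which both rose (2.03 ± 0.19 and 2.22 ± 0.25, edgeR adjusted p 0.00166 and 0.00278). Hepatocyte secreted proteins and identity factors fell in 4 of 21 cases (9 adjusted over the list alone; median -0.76, camera adjusted p = 4.7e-05, and adjusted p = 0.184 with an estimated correlation). Their number was 9 and 8 without control replicates 1 and 2, 0 without tumour replicate 1, and 10 with the mouse as a block.

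**Figure D3:**
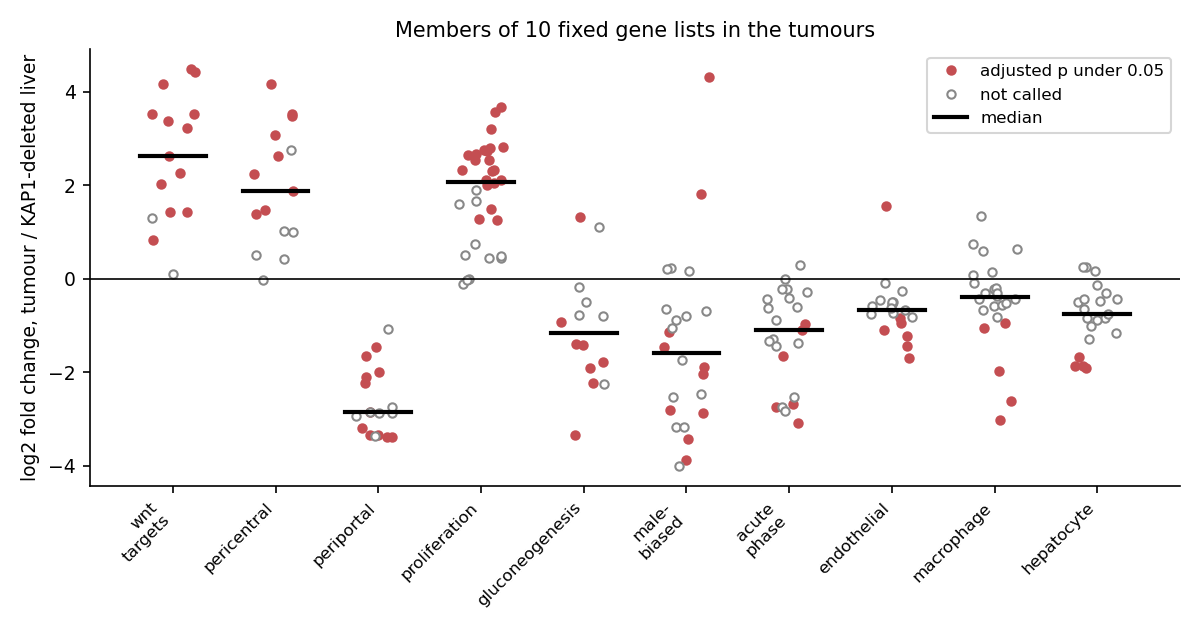
Log2 fold change of tumour against KAP1-deleted liver for the tested members of 10 gene lists, with filled points for genes past the threshold, open points for the rest and bars at the median. The medians of Wnt targets and pericentral markers were 2.62 and 1.87, and that of periportal markers -2.86.

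Proliferation genes rose in 21 of 32 cases and fell in 0 (24 adjusted over the list alone). They had a median of 2.07 (camera adjusted p = 1.5e-20, and adjusted p = 0.184 with an estimated correlation), and the number that rose was 13 without either KAP1-deleted replicate. Ccnb1, the mitotic cyclin B1, rose 11.9-fold (log2 fold change 3.57 ± 0.45, adjusted p = 0.00409). Prc1, a microtubule bundler of cytokinesis, rose (log2 fold change 2.82 ± 0.31, adjusted p = 0.00254). So did the spindle checkpoint kinase Ttk (3.67 ± 0.47) and the spindle motor Kif11 (2.10 ± 0.27), with edgeR adjusted p 0.00431 and 0.00434. The list of oncofetal and liver tumour markers was not called (camera adjusted p = 0.401, and 0.0222 without tumour replicate 1) and had members on both sides, a median of -0.30 and a mean of 0.28. Within it, Afp, alpha-fetoprotein, rose from 3.39 ± 1.11 to 11.7 ± 2.28 CPM (log2 fold change 1.78 ± 0.28, adjusted p = 0.00918). Golm1, a Golgi membrane protein, rose 5.46-fold (log2 fold change 2.45 ± 0.27, adjusted p = 0.00264). Gpc3, the oncofetal glypican 3, averaged 28.3 ± 12.9 against 0.456 ± 0.195 CPM (log2 fold change 5.94 ± 0.69, adjusted p = 0.00599). For Gpc3 the adjusted p was 0.0935 and 0.0983 without KAP1-deleted replicates 1 and 2 (range 4.8e-72 to 0.0983 over the alternatives).

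Cytochrome P450 genes of families Cyp1 to Cyp3, which oxidise drugs and steroids, went both ways, with 17 of 47 higher and 4 lower (21 rose and 7 fell adjusted over the list alone). The median was 0.25 (camera adjusted p = 2.9e-04, and adjusted p = 0.376 with an estimated correlation). Those that rose numbered 9 without KAP1-deleted replicate 1, and 9 without tumour replicate 1. Those that fell numbered 1 without either KAP1-deleted replicate, 0 without tumour replicate 1, and 8 with the mouse as a block. Cyp2c38 and Cyp2c69 rose (2.46 ± 0.25 and 1.61 ± 0.19, edgeR adjusted p 0.00200 and 0.00297). Cyp2a5, a coumarin hydroxylase on the pericentral list, rose 8.46-fold (log2 fold change 3.08 ± 0.46, adjusted p = 0.00778). Only 35.1% and 45.4% of the words of Cyp2c69 and Cyp2a5 are unique and their values are uncertain for that reason. Male-biased genes fell in 8 of 24 cases and rose in 2 (2 rose and 13 fell adjusted over the list alone). The male-biased median was -1.60 (camera adjusted p = 1.9e-05, and adjusted p = 0.376 with an estimated correlation). Cyp4a12a, a male-biased fatty acid hydroxylase, fell (log2 fold change -2.05 ± 0.27, adjusted p = 0.00500). Only 37.8% of the words of Cyp4a12a are unique, so its value is uncertain too. The male-biased count of falls was 3 and 2 without KAP1-deleted replicates 1 and 2, 4 without tumour replicate 1, and 16 with the mouse as a block. The count of rises was 1 without KAP1-deleted replicate 1, and 0 without either tumour replicate. The female-biased list was not called (camera adjusted p = 0.357). Its member Prlr, the prolactin receptor, fell (log2 fold change -2.24 ± 0.25, adjusted p = 0.00278), and Slco1a4, an organic anion transporter, rose (log2 fold change 2.58 ± 0.36, adjusted p = 0.00560).

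Markers of non-parenchymal cells were measured in the same libraries. Endothelial markers fell in 6 of 19 cases and rose in 1 (1 rose and 14 fell adjusted over the list alone). The endothelial median was -0.68 (camera adjusted p = 6.9e-05, and adjusted p = 0.376 with an estimated correlation). The endothelial falls numbered 10 without control replicate 1, 3 without either KAP1-deleted replicate, 2 and 1 without tumour replicates 1 and 2, and 11 with the mouse as a block. The rises numbered 0 without either KAP1-deleted replicate, and 0 without tumour replicate 1. Clec4g, a lectin of liver sinusoidal endothelium, fell (log2 fold change -1.45 ± 0.26, adjusted p = 0.0131). Macrophage and Kupffer cell markers fell in 5 of 24 cases (6 adjusted over the list alone; median -0.39, camera adjusted p = 0.00536, and adjusted p = 0.648 with an estimated correlation). Their camera adjusted p was 0.252 without tumour replicate 1 (range 5.4e-06 to 0.648 over the alternatives). Their falls numbered 2 and 3 without KAP1-deleted replicates 1 and 2, and 3 without tumour replicate 1. The Kupffer cell genes Clec4f and Timd4 fell (-1.97 ± 0.18 and -2.61 ± 0.42, edgeR adjusted p 0.00150 and 0.0102). Markers of other cell types were not called. Their camera adjusted p was 0.0628 (0.00129 without KAP1-deleted replicate 2, 0.00101 without tumour replicate 1, and 0.0123 with the mouse as a block) for lymphocytes and 0.244 for neutrophils. Of 22 lymphocyte markers 17 had a log2 fold change above 0, with a median of 0.80. By edgeR 0 were called (0 adjusted over the list alone), 6 higher ones and 2 lower ones had an unadjusted p under 0.05, DESeq2 called 2 higher and 2 lower and limma-voom 0 and 0. With the mouse as a block 6 rose, and 3 fell without KAP1-deleted replicate 1. The camera adjusted p was 0.123 (0.00292 without tumour replicate 2) for cholangiocytes, 0.289 (0.00333 with the mouse as a block) for adipocytes and 0.997 for stellate cells and matrix. For red blood cells it was 0.108 (1.2e-05 without KAP1-deleted replicate 1, and 0.0183 with the mouse as a block). Of the exocrine pancreas list 3 genes were tested, too few for a set test. The 14 genes of the list summed to 5.06 and 8.15 CPM without TMM scaling in control livers 1 and 2, 4.47 and 35.3 in KAP1-deleted livers 1 and 2, and 41.1 and 296 in tumours 1 and 2. By edgeR 0 of the 3 were called in KAP1-deleted against control liver, with 0 at an unadjusted p under 0.05 and 0 by DESeq2 and limma-voom. In tumour against either liver group edgeR called 0, with 1 at an unadjusted p under 0.05, and DESeq2 called 1 higher and limma-voom 0 (1 adjusted over the list alone against control liver and 0 against KAP1-deleted liver). Without KAP1-deleted replicate 1, where the filter on low counts let more of the list through, 10 fell in tumour against KAP1-deleted liver and 6 rose in KAP1-deleted against control liver. Without tumour replicate 1, 2 rose in tumour against either liver group, and 2 rose against KAP1-deleted liver with the mouse as a block. Pnliprp1, a pancreatic lipase-related gene, averaged 113 ± 129.6 against 1.14 ± 1.59 CPM (edgeR adjusted p = 0.0935, and 0.00283 with the mouse as a block). The share of counted reads outside any gene was 31.3% and 35.0% in the tumours against 18.0% to 25.2% in the 4 livers.

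NRF2 targets, genes of the oxidative stress response, rose in 5 of 21 cases and fell in 1 (6 rose and 1 fell adjusted over the list alone). The NRF2 list had a median of 0.54 (camera adjusted p = 0.0129, and adjusted p = 0.648 with an estimated correlation). Their adjusted p was 0.0920 without KAP1-deleted replicate 1 (range 7.8e-05 to 0.648 over the alternatives). Rises numbered 0 without either KAP1-deleted replicate, and 3 without tumour replicate 1. Falls numbered 3 and 2 without control replicates 1 and 2, and 3 with the mouse as a block. Ugdh, UDP-glucose dehydrogenase, was the member that fell (log2 fold change -1.65 ± 0.21, adjusted p = 0.00416). Genes of the unfolded protein and integrated stress response rose in 4 of 23 cases and fell in 0 (6 adjusted over the list alone). They had a camera adjusted p = 0.0129, and adjusted p = 0.648 with an estimated correlation. The list's camera adjusted p was 0.0525 without KAP1-deleted replicate 1, and 0.433 without tumour replicate 2 (range 1.4e-06 to 0.648 over the alternatives). Its rises numbered 2 without KAP1-deleted replicate 1. Its falls numbered 1 without either control replicate, 1 without tumour replicate 2, and 1 with the mouse as a block. Psat1, of serine synthesis, rose 21.1-fold (log2 fold change 4.40 ± 0.33, adjusted p = 9.1e-04). Trib3, a pseudokinase induced by stress, rose 7.84-fold (log2 fold change 2.97 ± 0.39, adjusted p = 0.00494). Acute phase proteins fell in 6 of 23 cases (13 adjusted over the list alone; median -1.10, camera adjusted p = 3.1e-06, and adjusted p = 0.376 with an estimated correlation). The falls numbered 1 without either KAP1-deleted replicate, and 2 and 10 without tumour replicates 1 and 2. Glycolysis genes fell in 3 of 20 cases (6 adjusted over the list alone; median -0.59, camera adjusted p = 0.00495, and adjusted p = 0.648 with an estimated correlation). For glycolysis the camera adjusted p was 0.148 without tumour replicate 1 (range 4.8e-04 to 0.648 over the alternatives). Glycolysis falls numbered 6 without either control replicate, 1 without either KAP1-deleted replicate, 1 without either tumour replicate, and 7 with the mouse as a block. Pdk1, a kinase that inhibits pyruvate dehydrogenase, was among them (log2 fold change -1.62 ± 0.21, adjusted p = 0.00419).

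Other lists were not called between tumour and KAP1-deleted liver. Their camera adjusted p was 0.0929 for KAP1 and its chromatin partners, 0.461 for Zfp genes and 0.144 (0.00782 without tumour replicate 1) for imprinted genes. It was 0.480 for germline genes, 0.496 for interferon-stimulated genes, 0.774 for fatty acid oxidation, 0.123 for p53 targets, 0.134 for ribosomal proteins and 0.0660 (0.00832 without tumour replicate 1) for the circadian clock. For bile acid synthesis and transport it was 0.0875 (0.0271 without KAP1-deleted replicate 1, 0.0481 without tumour replicate 1, and 0.0206 with the mouse as a block). For lipid droplet genes it was 0.108 (0.0207 and 0.0191 without control replicates 1 and 2, 0.0248 without KAP1-deleted replicate 1, 0.0478 without tumour replicate 1, and 0.00155 with the mouse as a block). For cholesterol synthesis it was 0.0875 (0.0359 and 0.0303 without control replicates 1 and 2, 6.4e-05 without KAP1-deleted replicate 2, 0.0237 without tumour replicate 1, and 0.0300 with the mouse as a block). In the imprinted list, Airn, the non-coding transcript antisense to Igf2r, rose 27.1-fold (log2 fold change 4.76 ± 0.41, adjusted p = 0.00120), which is uncertain because the strand setting of the counting is not given in the sources used here.

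Greb1, an estrogen-responsive gene, rose 197-fold from 0.0863 ± 0.0578 to 17.7 ± 7.60 CPM (log2 fold change 7.62 ± 0.55, adjusted p = 7.2e-04). Akr1b7, an aldose reductase-like enzyme, rose 132-fold to 6.12 ± 4.84 CPM (log2 fold change 7.04 ± 0.81, adjusted p = 0.00323). Hsd3b1, a 3-beta-hydroxysteroid dehydrogenase, had 1 count in the KAP1-deleted livers together and 6.13 ± 1.39 CPM in tumour, a count ratio of 573 with a 95% counting interval of 103 to 22670.0 (edgeR adjusted p = 0.00116). At the low end lay 7 major urinary protein genes (Mup1, Mup2, Mup8, Mup9, Mup13, Mup16 and Mup19), pheromone carriers, with log2 fold changes of -3.88 to -3.79 and edgeR adjusted p of 0.0300 to 0.0407. Without KAP1-deleted replicate 1 their adjusted p was 0.150 to 0.207, without KAP1-deleted replicate 2 0.139 to 0.213 and without tumour replicate 1 0.0867 to 0.108. Over the alternatives it lay between 4.4e-30 and 0.213. Only 29.8% of the words of Mup1 and 4.88% of those of Mup13 are unique, so reads cannot be assigned to single Mup genes with certainty.

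In all, 842 genes rose and 1165 fell in tumour against KAP1-deleted liver, 708 and 856 of them by at least 2-fold. With the mouse as a block, which leaves 1 residual degree of freedom, 1571 rose and 2318 fell. Higher genes made up 42.0% of these calls, and 52.0% with upper-quartile scaling. Without KAP1-deleted replicates 1 and 2 the counts were 338 and 496, and 295 and 345 higher and lower. Without tumour replicates 1 and 2 they were 472 and 265, and 520 and 664. Of the 35 lists tested 15 were called, and 21 with the mouse as a block.

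Against control liver the tumours differ in both KAP1 deletion and tumour state, and the genes at the ends of the range included many of those seen in KAP1-deleted liver. Fbxw19 averaged 15.0 ± 0.773 CPM, at least 466-fold higher than in control liver, where both libraries held 0 counts (edgeR adjusted p = 8.3e-04). Fbxw16 was at least 204-fold higher (edgeR adjusted p = 6.8e-04). Cdhr2 rose from 0.0543 ± 0.00481 to 58.0 ± 17.1 CPM (log2 fold change 10.02 ± 0.46, adjusted p = 9.8e-05). Rarres1 fell to 0.359 ± 0.273 CPM (log2 fold change -7.73 ± 0.56, adjusted p = 8.3e-04) and Cyp7b1 to 10.7 ± 0.0323 CPM (log2 fold change -4.16 ± 0.40, adjusted p = 0.00139). So did the inflammasome-related gene Nlrp12 (-5.68 ± 0.47) and the glutamate receptor gene Grm8 (-5.02 ± 0.53), with edgeR adjusted p 0.00110 and 0.00159. Trim24 rose (log2 fold change 1.88 ± 0.26, adjusted p = 0.00433).

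Of 330 Zfp genes tested, 38 rose and 9 fell (38 rose and 9 fell adjusted over the list alone). Many of those that rose lie in the chromosome 4 stretch described above, whose raised genes mostly share words with each other. There 1 signal can be counted several times. The Zfp list had a camera adjusted p = 0.00122, and adjusted p = 0.632 with an estimated correlation. Its adjusted p was 0.0828 without control replicate 2 (range 2.1e-05 to 0.632 over the alternatives). The Zfp rises numbered 22 without control replicate 2, and 22 without tumour replicate 1. The Zfp falls numbered 4 and 3 without control replicates 1 and 2, 5 without KAP1-deleted replicate 2, and 4 and 3 without tumour replicates 1 and 2. Zfp987 rose 21.9-fold (log2 fold change 4.45 ± 0.34, adjusted p = 5.8e-04). Zfp992 rose 9.18-fold (log2 fold change 3.20 ± 0.29, adjusted p = 9.5e-04). Only 6.85% of the words of Zfp987 and 50.1% of those of Zfp992 occur in no other gene, so both values are uncertain. Male-biased genes fell in 12 of 24 cases and rose in 2 (3 rose and 15 fell adjusted over the list alone). Their median was -2.10 (camera adjusted p = 5.5e-07, and adjusted p = 0.337 with an estimated correlation). Their falls numbered 5 without control replicate 1, 6 without either KAP1-deleted replicate, and 7 without tumour replicate 1. The male-biased rises numbered 0 without either control replicate, and 0 without either tumour replicate. Female-biased genes rose in 10 of 27 cases and fell in 1 (11 rose and 6 fell adjusted over the list alone). The female-biased median was 0.85 (camera adjusted p = 0.00682, and adjusted p = 0.223 with an estimated correlation). The camera adjusted p of the female-biased list was 0.141 without control replicate 1, and 0.0525 without tumour replicate 2 (range 1.6e-04 to 0.223 over the alternatives). The female-biased rises numbered 6 without tumour replicate 1, and the falls 2 without either control replicate, and 2 and 3 without tumour replicates 1 and 2. Cyp2a4, a steroid 15-alpha-hydroxylase with female-biased expression, rose (log2 fold change 3.68 ± 0.44, adjusted p = 0.00315). The male-biased genes Susd4 and Ugt2b38, a glucuronosyltransferase, fell (-4.43 ± 0.59 and -1.25 ± 0.19, edgeR adjusted p 0.00583 and 0.00603). Cyp2a4 and Ugt2b38 share most of their sequence words with other genes, and their values are uncertain.

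Wnt targets rose in 12 of 15 cases (13 adjusted over the list alone; camera adjusted p = 8.3e-26, and adjusted p = 0.176 with an estimated correlation). Pericentral markers rose in 9 of 15 (11 adjusted over the list alone; camera adjusted p = 1.9e-11, and adjusted p = 0.236 with an estimated correlation). Proliferation genes rose in 19 of 32 (24 adjusted over the list alone; camera adjusted p = 3.8e-15, and adjusted p = 0.223 with an estimated correlation). Rnf43, a ubiquitin ligase of the Wnt pathway, rose 5.03-fold (log2 fold change 2.33 ± 0.19, adjusted p = 7.4e-04). Mki67, the Ki-67 antigen of cycling cells, rose 5.28-fold (log2 fold change 2.40 ± 0.30, adjusted p = 0.00314). Periportal markers fell in 11 of 18 cases (1 rose and 17 fell adjusted over the list alone; camera adjusted p = 7.9e-13, and adjusted p = 0.202 with an estimated correlation). Among them was Arg1, arginase of the urea cycle (log2 fold change -3.26 ± 0.51, adjusted p = 0.00768). Gluconeogenesis and glycogen genes fell in 8 of 14 cases (1 rose and 9 fell adjusted over the list alone; camera adjusted p = 8.3e-06, and adjusted p = 0.176 with an estimated correlation). The falls numbered 3 and 5 without tumour replicates 1 and 2. Tat, tyrosine aminotransferase, fell (log2 fold change -3.48 ± 0.38, adjusted p = 0.00179). Fatty acid and triglyceride synthesis genes fell in 6 of 22 cases (1 rose and 14 fell adjusted over the list alone; camera adjusted p = 2.5e-06, and adjusted p = 0.176 with an estimated correlation). They included Srebf1, a transcription factor of lipogenesis (log2 fold change -1.69 ± 0.23, adjusted p = 0.00383), and Fasn, fatty acid synthase (log2 fold change -1.71 ± 0.25, adjusted p = 0.00533). Cholesterol genes fell in 4 of 22 cases (7 adjusted over the list alone; camera adjusted p = 5.4e-06, and adjusted p = 0.570 with an estimated correlation), or 1 without tumour replicate 2.

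Further lists called lower in tumour against control liver were acute phase proteins (camera adjusted p = 8.2e-06), hepatocyte proteins (6.2e-05), endothelial markers (9.8e-04) and macrophage markers (0.00445). So were glycolysis (0.00682), circadian genes (0.0163), bile acid genes (0.0289) and ribosomal proteins (0.0495). Cytochrome P450 genes (5.1e-04), NRF2 targets (0.0206), stress response genes (0.0317) and lymphocyte markers (0.00843) were called higher. For these 12 lists the adjusted p was 0.223 to 0.658 with an estimated correlation. The adjusted p of macrophage markers was 0.186 without tumour replicate 1 (range 5.4e-06 to 0.632 over the alternatives). For glycolysis it was 0.194 without control replicate 2, and 0.156 without tumour replicate 1 (range 2.9e-05 to 0.658 over the alternatives), and for circadian genes 0.143 without tumour replicate 2 (range 0.00182 to 0.337 over the alternatives). For ribosomal proteins the values were 0.0511 and 0.0670 without control replicates 1 and 2, 0.0535 without KAP1-deleted replicate 1, and 0.129 and 0.0625 without tumour replicates 1 and 2 (range 0.00792 to 0.632 over the alternatives), and 0.0649 with the mouse code series as a block. The call of the ribosomal proteins also ended with DESeq2 size factors, with upper-quartile scaling and with a mean CPM of at least 5. The values of NRF2 targets were 0.422 without control replicate 1 (range 8.0e-07 to 0.654 over the alternatives). Stress response genes had 0.0826 and 0.0660 without control replicates 1 and 2, and 0.659 without tumour replicate 2 (range 2.5e-05 to 0.659 over the alternatives). Lymphocyte markers had 0.0933 without control replicate 2, and 0.201 without tumour replicate 2 (range 1.5e-04 to 0.632 over the alternatives). The other 13 lists had camera adjusted p of 0.100 to 0.821. Among them, with values in parentheses where leaving out a library brought a call, were interferon-stimulated genes at 0.100 (0.00126 without control replicate 1, and 0.00673 without tumour replicate 2), lipid droplet genes at 0.292 (0.00148 without control replicate 1) and adipocyte markers at 0.217 (0.00224 without control replicate 1). Stellate cell and matrix markers stood at 0.819 (0.00446 without control replicate 2), p53 targets at 0.137 (0.00925 without control replicate 2) and cholangiocyte markers at 0.584 (0.0296 without tumour replicate 2). Red blood cell markers stood at 0.249 (0.0381 and 0.0348 without KAP1-deleted replicates 1 and 2), imprinted genes at 0.434 (0.0130 without tumour replicate 1) and oncofetal markers at 0.479 (0.0368 without tumour replicate 1).

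In all, 1080 genes rose and 1363 fell in tumour against control liver, 908 and 973 of them by at least 2-fold. Higher genes made up 44.2% of the calls, and 51.9% with upper-quartile scaling, which called 1200 and 1112. The counts were 696 and 733 without control replicate 2, and 663 and 440, and 680 and 719 without tumour replicates 1 and 2. Of the 35 lists 22 were called, and between 19 and 23 when single libraries were left out.

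How far the KAP1-deleted livers and the tumours shared a response was tabulated over 17558 genes. Of the 42 genes that rose in KAP1-deleted liver, 41 also rose in tumour against control, where independent lists would share 2.58. Of the 17 that fell, 16 also fell, against 1.32. Their median log2 fold changes were 3.26 and -2.81 in KAP1-deleted liver and 3.91 and -3.59 in tumour. Between tumour and KAP1-deleted liver, 5 of the 42 rose and 4 fell, and of the 17, 2 rose and 6 fell. Both comparisons used the same 2 control libraries, which the simulations take into account and the independent lists do not. The KAP1-deleted livers and tumours came from the same 2 mice, which neither the simulations nor the independent lists take into account. In 20 simulations of unchanged groups against 2 shared control libraries, a mean of 0 and 0 genes were called higher and lower in both with trended dispersions. With gene-wise dispersions the means were 0.550 and 0.250. Across genes, which are not independent replicates, the log2 fold changes correlated with r = 0.472, against a simulated 0.511 and 0.510. Their covariance was 0.370, against 0.0920 and 0.0992, a difference of 0.278 and 0.271. In all 59.1% of genes had the same sign against 67.0% and 66.8%. The simulations gave every group the same spread per gene and no changed genes. In the data the control pair differed most, with a chi-square per degree of freedom of 352, against 90.8 for KAP1-deleted livers and 150 for tumours. The correlation, covariance and share of signs are therefore not compared like with like. With control replicate 1 for the KAP1-deleted livers and control replicate 2 for the tumours, a split added after seeing the data, 17 genes were called higher and 10 lower in both, where independent lists would share 1.37 and 1.59, and the covariance was 0.238. The other way round 17 and 9 were called in both, against 0.829 and 0.572, with a covariance of 0.289. Each comparison then rests on a lone control that is assumed to vary like the other groups. Without control replicates 1 and 2 the genes called higher and lower in both numbered 19 of 20 and 12 of 14, and 25 of 26 and 16 of 20, out of those called in KAP1-deleted liver. Without KAP1-deleted replicates 1 and 2 they numbered 36 of 64 and 10 of 11, and 49 of 52 and 11 of 13. Without tumour replicates 1 and 2 they numbered 22 of 22 and 7 of 8, and 20 of 23 and 7 of 8. DESeq2 gave 114 of 152 and 54 of 78, and no filter on low counts 213 of 354 and 160 of 217.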

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

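The tests of the chromosome of Trim28, scaling, cell type markers and pericentral genes in this part were chosen only after the result was seen. Reads outside any gene made up 33.1% ± 2.64 of the counted reads in tumours, 21.6% ± 5.06 in control livers and 20.2% ± 2.96 in KAP1-deleted livers (SD, n = 2 each). This share stands out because it comes from an entry that no comparison uses and lies above the control level. It was 31.3% and 35.0% in the tumours and at most 25.2% in a liver, and no cause was tested.

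The rise of Zfp genes in KAP1-deleted liver sat mostly in 1 place. Of 39 raised genes with a position, 16 lay on chromosome 4, which holds 1157 of the tested genes, and most of these share words with each other, so that 1 signal can be counted several times. Strain DNA kept around the altered Trim28 gene is argued against, since 0 of the 12 raised Zfp genes lie on its chromosome, 7, but strain DNA elsewhere was not tested. Reads shared with another raised gene stay open as a partial source, because only 1 of the 12 shares under 5% of its words, a low limit, with another raised gene and 0 of the 12 are mostly unique (at least 80% of words in no other gene). Loss of KAP1 repression at this stretch may account for the rise as a biological candidate, and how many of the 15 raised genes of the stretch rose on their own cannot be counted from shared reads (4 and 6 were called without control replicates 1 and 2, and 7 without either tumour replicate).

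Wnt targets and pericentral genes rose in tumour against KAP1-deleted liver. Scaling differences of the size seen between the methods tried are argued against, as the lowest count of raised Wnt targets over them was 13 of 15. Those methods moved the median log2 fold change of all genes only between -0.0346 and 0.0586, while the Wnt targets had 2.62. They could hardly have undone the calls, and a larger scaling error common to them was not tested. A lower share of hepatocytes alone, with all other cell types kept in proportion, would raise the markers of every other cell type. Instead 10 more endothelial and macrophage markers were called lower than higher, or 16 with the mouse as a block. The number fell below 5, the limit set for this test, when tumour replicate 1 or 2 was left out. The hepatocyte list itself had a median of -0.76. Several cell types may be fewer at once, so these markers cannot decide on the share of hepatocytes. Lymphocyte markers had a median of 0.80. Pancreas genes summed to 41.1 and 296 CPM without TMM scaling in tumours 1 and 2, and to 35.3 in KAP1-deleted liver 2. Such a sum does not show that each member rose. More lymphocytes or pancreatic tissue in the tumours stay open. More pericentral tissue in the tumour samples cannot be told apart from Wnt activation, since the 12 Wnt targets outside the pericentral list had a median of 2.14, near the 1.87 of the pericentral list, and no value separates these. A gain of Wnt signalling in the tumours is a hypothesis that may be followed up with the sequence of Ctnnb1 and Apc, which was not analysed here.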

How the results depend on the processing

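The mouse code series block, the restriction to mostly unique genes and the split of the controls were chosen only after the data were seen; the other choices were made before the data were examined. Genes called are given as higher and lower. Without a filter on low counts (27238 genes) 354 and 217 were called in KAP1-deleted against control liver, 1563 and 2256 in tumour against KAP1-deleted liver, 1801 and 2314 in tumour against control liver, and 213 and 160 in both comparisons with control. With a mean CPM of at least 5 (9245 genes) these were 13 and 4, 485 and 743, 556 and 876, and 13 and 4, with fewer genes to call. DESeq2 called 152 and 78 in KAP1-deleted against control liver and 114 and 54 in both. Limma-voom called 26 higher there and 26 higher in both. With only the groups compared (2 residual degrees of freedom) 13 and 7 were called there, and 11 and 7 in both. For these tools and samples the cause was not tested.

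With the mouse as a block 1571 and 2318 genes were called in tumour against KAP1-deleted liver, from fewer residual degrees of freedom than in the main fit. The block changed no other call printed than those given beside their values. A block of mice with codes of the same series gave 70 and 27 in KAP1-deleted against control liver and 65 and 25 in both. It followed a correlation of deviations across genes of 0.386 between control and KAP1-deleted livers and 0.0854 between control livers and tumours. With this block the male-biased list in KAP1-deleted against control liver (adjusted p = 0.0917) and ribosomal proteins in tumour against control liver (0.0649) were no longer called, and the cause was not tested. Mostly unique genes alone gave 11 and 9 in KAP1-deleted against control liver, although 29 of the 59 genes called among all are mostly unique. The p-values were kept and only adjusted anew over this subset, so the drop comes from the adjustment. Of the 59 called genes 56 had a value of sequence sharing, of which 29 were mostly unique. Among tested genes with a value 80.8% were, so called genes shared sequence more often.

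With single libraries left out, where the lone library of a group is assumed to vary like the other groups, KAP1-deleted against control liver gave 20 to 64 genes higher and 8 to 20 lower. Tumour against KAP1-deleted liver gave 295 to 1093 and 265 to 1684, and tumour against control liver 663 to 998 and 440 to 1623. In both comparisons with control 19 to 49 and 7 to 16 were called, and with each control in 1 comparison only 17 and 10, or 17 and 9. Lists called numbered 5 to 11, 15 to 20 and 19 to 23 in the 3 comparisons. An estimated correlation left 0, 0 and 0 lists called by camera (1, 7 and 7 at an unadjusted p under 0.05), where the preset one called 4, 15 and 22. Fry called 0 in KAP1-deleted against control liver (1 at an unadjusted p under 0.05), 10 in tumour against KAP1-deleted liver and 13 in tumour against control liver, of which 0, 8 and 13 were among the 4, 15 and 22. Of the 4, 15 and 22, 4, 14 and 18 stayed called with a mean CPM of at least 5, and 4, 15 and 21 with either DESeq2 size factors or upper-quartile scaling.

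DESeq2 size factors, upper-quartile scaling and leaving out the 20 most abundant genes moved each count of called genes by under 1.5 times. Of 272 calls of named genes, 0 turned direction under any setting. Lost were 1 with DESeq2 size factors, 9 with upper-quartile scaling, 16 with limma-voom, 12 with voom and the mouse as a random block, 1 with the code series block, 30 with only the groups compared, and 9 of 210 with a mean CPM of at least 5. Losses were 42 and 58 without control replicates 1 and 2, 73 and 72 without KAP1-deleted replicates 1 and 2, and 108 and 76 without tumour replicates 1 and 2. With the mouse as a block 4 of 119 were lost, none of them named in the text. At this depth and with 2 libraries per group a 2-fold change was called in 12.7% to 30.4% of simulated cases with trended dispersions, so a missing call does not show that a gene was unchanged.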

Other observations

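Groups of genes by shared name stem (487 stems with at least 5 tested genes) were compared only after the data were seen, as were the tests of Mup genes and of parts of chromosome 4, while the test of GC content was set before its result. In tumour against KAP1-deleted liver 11 of 33 kinesin genes (Kif), motor proteins many of which act in mitosis, rose (hypergeometric adjusted p = 7.6e-05), among them Kif14, Kif20a and Kif23, named after their values were seen. The number was 10 without either control replicate, 5 and 7 without KAP1-deleted replicates 1 and 2, and 7 and 6 without tumour replicates 1 and 2. Of 81 Cyp genes 19 rose (hypergeometric adjusted p = 5.8e-06), and 11 and 13 did without KAP1-deleted replicates 1 and 2 and 11 without tumour replicate 1. Of 11 Ndufb genes, of complex I of the respiratory chain, 6 fell (hypergeometric adjusted p = 0.00927), as did 8 of 23 genes with the stem Cox (hypergeometric adjusted p = 0.0164). The Ndufb count was 9 without either control replicate, 1 and 0 without KAP1-deleted replicates 1 and 2, 0 without either tumour replicate, and 9 with the mouse as a block. The Cox count was 11 without either control replicate, 3 and 1 without KAP1-deleted replicates 1 and 2, 0 and 1 without tumour replicates 1 and 2, and 11 with the mouse as a block. Of 17 Mup genes 11 fell (hypergeometric adjusted p = 7.6e-07), 0 without either KAP1-deleted replicate and 1 without tumour replicate 1. Mup1 and Mup13 share most of their words with other genes, so Mup genes are not independent in this test. The same holds for Cyp2c40, Cyp2c69 and Cyp2a5 among the Cyp genes that rose. Genes of the other stems may also change together, so the hypergeometric p-values may be too small.

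Genes of chromosome 4 were lower in both tumours, a pattern noticed while browsing, with median log2 values of -0.246 (bootstrap bounds -0.288 to -0.202) and -0.166 (-0.226 to -0.118) in tumours 1 and 2 over 589 genes, the lowest of 20 chromosomes in both. The next lowest stood at -0.0699 and -0.129, and the 4 livers lay between -0.0197 and 0.011 on chromosome 4, with 141 genes of the chromosome called lower and 34 higher in tumour against KAP1-deleted liver (46 lower and 8 higher, and 33 and 10, without KAP1-deleted replicates 1 and 2, 29 and 14, and 80 and 18, without tumour replicates 1 and 2, and 239 lower and 66 higher with the mouse as a block). In tumour 2 the X chromosome and chromosome 3 lay about as far above 0, at 0.192 and 0.155, while no chromosome exceeded 0.0779 in tumour 1. Other chromosomes of the livers ranged from -0.141 to 0.12. A trend on GC content and the Mup genes alone are argued against as the whole of the shift below 0. The higher tumour median, that of tumour 2, was -0.143 (-0.185 to -0.111) after the trend was taken out and -0.143 (-0.201 to -0.109) without 20 Mup genes. Both bounds include -0.129, the uncorrected next lowest chromosome in tumour 2, so chromosome 4 did not stand clear of it there. The bounds take genes as independent and may be too narrow, since neighbouring genes changed together. In tumour against KAP1-deleted liver 169 adjacent pairs were lower and 131 higher, against permuted means of 76.9 and 38.8. Fewer copies of chromosome 4 in the tumour cells may explain the pattern as a hypothesis. In both tumours 8 of 8 equal parts of the chromosome had a median below 0, from -0.607 to -0.0847 in tumour 1 and from -0.587 to -0.00241 in tumour 2. In the 4 livers 2 to 5 of 8 did, and their parts lay between -0.291 and 0.188. The chromosome was picked as the lowest in these same tumours, and no other chromosome was divided into parts. The count of parts below 0 follows largely from that choice and cannot decide on copies. RNA does not measure copies, several tumour parts lay within the range of the livers' parts, and DNA of the tumours was not analysed here.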
